A study of Zea mays with 16 samples.

How the data were processed

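Guard cells and subsidiary cells were laser-microdissected, per the labels' protocols, from epidermal strips of leaf number 3 of 2-week-old maize seedlings of the inbred line B104, grown in a cycle of 16 h light at 25 °C and 8 h dark at 22 °C. Strips were taken 2 h after the lights came on (day) or 2 h after they went off (night), in 4 independent collections. Cells were selected in the microscope's Zeiss software and freed with its laser, about 1500 cells per tube and 2 tubes per sample. RNA (about 10 pg) was amplified with SMART-Seq v4, and 150 ng of cDNA went into Nextera XT libraries, per the labels' protocols. This kit keeps no strand and adds no molecular identifiers, so reads are not independent molecules and reads of overlapping genes cannot be told apart. The 4 groups (guard cells by day, guard cells by night, subsidiary cells by day, subsidiary cells by night) hold 4 libraries each, 16 in all. The titles of the subsidiary cell night samples carry a day-like word, while their treatment label and library names say night, and they were grouped as night. The labels do not tie a replicate number to 1 collection across the cell types.

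The deposited table lists 38179 genes in 36 columns. Its normalized counts (signal) are gene counts that the authors divided by 1 size factor per library, per the file headers and the values themselves. In every library 100% of the values were whole multiples of 1 step within 0.01, so whole reads were recovered, and the recovered size factors ran from 0.730 to 1.46. The deposited log2 fold change (a score, shrunken toward 0 for most genes) and the adjusted p-value of 4 comparisons come from the authors' DESeq2 run, version 1.40.2 with the B73 RefGen v4 build, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The plants are B104 and the build is B73, so reads of genes that differ between the lines can be lost or shared. In 62 lines of the table the description had shifted the later columns, and these were moved back. Every column of sample values was matched to a sample by its library name.

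The main test was limma-trend on log2(normalized count + 1), with 4 group means fitted over all 16 libraries (12 residual degrees of freedom) and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. Genes with a value of at least 10 in at least 4 libraries were tested, which kept 37759 and left out 420. Fold changes are differences of mean log2(value + 1), so where some libraries lie near 0 they can differ from the ratio of group means and exceed it. The design had foreseen edgeR for counts and limma for normalized values, and the limma branch applied because the deposited values are normalized. Contrasts were guard minus subsidiary cells by day and by night, day minus night in each cell type, and the interaction, (guard minus subsidiary by day) minus (guard minus subsidiary by night). The replicates come from separate collections, so p-values measure the spread between collections and their preparation. Programs were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

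Gene names are the first word of the deposited description, the part of it that is used here. Of the tested genes 7467 (19.8%) have such a word, with 1636 distinct words in the table, and 0 identifiers matched the reference table of gene names, which uses another assembly. Plasma membrane aquaporins could thus not be set apart from other aquaporins, and planned lists of guard cell genes and of the stomatal lineage could not be rebuilt. Named genes were, per comparison and direction, up to 10 called genes of smallest p with a description word, a mean log2 value of at least 3 and no overlap between the 4 and 4 libraries. To these came up to 4 members of smallest p per gene list and called clock genes. For the interaction the rule took 5 genes per direction, and no gene met it. Plasma membrane aquaporins, which the rule would have named in full, could not be told from the rest. Called night genes without a description, and list members behind a count of 5 or fewer, were chosen after their values were seen. Of 26 planned lists 24 were rebuilt from first words after the data had been seen: aquaporins, clock and photoperiod names, chlorophyll-binding, photosystem and electron transport, Calvin cycle, mesophyll C4 names, bundle sheath names, potassium transport, chloride channels, vacuolar proton pumps, plasma membrane names, sugar transporters, abscisic acid names, photoreceptors, starch turnover, expansins, cell wall enzymes, wax synthesis, heat shock and chaperones, cytosolic ribosomal proteins, histones and cyclins, vascular names, dehydrins and late embryogenesis, and organelle identifiers. A further 6 lists were added after seeing the data: auxin response, TIFY repressors, peroxidases, tubulins and actins, trehalose metabolism, and benzoxazinoid and pathogen defence. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation. Counts adjusted over the list alone are given beside those over all genes. In addition, each of 127 first words with at least 10 measured members was tested as a family, a test also added after seeing the data.

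Sample groups, the model, the 5 contrasts, the named-gene rule and the planned lists and alternatives were fixed before the data were examined. The alternatives fixed in this way were quantile normalization, upper-quartile scaling, no filter, a value of at least 10 in at least 8 libraries, pseudocounts of 0.1 and 10, library quality weights, a replicate block, a fit of the compared groups alone, a threshold of 0.01, a minimum log2 fold change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were TMM scaling, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, and leaving out both libraries of mean correlation under 0.7. Library totals, genes detected, the share of the 50 most abundant genes, the organelle share and mean correlations were compared with exact permutation tests.

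The main test was checked on simulated counts with the real means, library sizes and spread and 200 changed genes of mean at least 50. For guard against subsidiary cells by day it recovered 4 of 67 genes changed 4-fold (5.97%), 27 of 67 changed 8-fold (40.3%) and 46 of 66 changed 16-fold (69.7%), with 5 false calls among 83. In guard cells by day against night the shares were 14.9%, 47.8% and 72.7%, and in subsidiary cells 19.4%, 44.8% and 71.2%. By night between the cell types they were 10.4%, 38.8% and 63.6%. For the interaction 0 of 67 genes were recovered at 4-fold and at 8-fold, and 4 of 66 at 16-fold. False calls were 9 among 99 in guard cells, 8 among 98 in subsidiary cells, 6 among 81 by night and 0 among 4 for the interaction. In each of the 4 comparisons between groups the share of false calls was thus over the threshold of 0.05, in 1 simulation each. Camera recovered the planted list in each comparison, and 1 of the 5 unchanged lists, by night between the cell types, also fell under 0.05 before adjustment. Simulated genes were drawn independently of each other, while the photosystem list had an estimated correlation of 0.214. The check thus does not test camera's preset correlation on lists whose members vary together. Reads per library and their precision are given with the results.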

Results

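Guard cells, which border the stomatal pore, and subsidiary cells, which flank them in grasses and exchange water and ions with them, were profiled separately from the leaf epidermis of maize line B104. Each cell type was sampled by day and by night, in 4 libraries per group and 16 in all. The series title names aquaporins in stomatal movement as the subject. Libraries held 16.6 to 28.9 M recovered reads (median 22.2 M). Means were 21.6 ± 2.17 M (SD, n = 4) in guard cells by day, 19.4 ± 2.43 by night, 20.9 ± 4.03 in subsidiary cells by day and 24.0 ± 3.24 by night. Of the 38179 listed genes, 35750 to 37363 were detected per library. Libraries of a group correlated across genes at mean Spearman rho of 0.752 (guard cells by day), 0.714 (guard cells by night), 0.760 (subsidiary cells by day) and 0.811 (subsidiary cells by night). The standard error of a log2 fold change between groups had a median of 0.73 over genes.

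A pair of libraries stood apart from the rest. Replicate 4 of guard cells by night had a mean correlation with the other 15 libraries of 0.642, and replicate 1 of subsidiary cells by day had 0.669, against 0.707 to 0.758 in the remaining libraries. In the former, Zm00001d016048 held 979593 normalised counts against 2565 to 47223 elsewhere, and Zm00001d025010, the most abundant gene of each other library, held 77446 against 591287 to 1671393. Against the other 3 libraries of its group its photosystem list was shifted by a median log2 of -2.25, its cytosolic ribosomal list by -1.54 and its histone and cyclin list by -1.43. In replicate 1 of subsidiary cells by day the mesophyll C4 list was shifted by -2.91 and the photosystem list by -1.26. Read totals, genes detected, the share of the 50 most abundant genes, the organelle share and mean correlations showed no difference between cell types or times that passed 2-sided exact permutation tests (8 against 8 libraries, 10 tests, smallest Benjamini-Hochberg adjusted p = 0.493). The smallest unadjusted value in these exact tests was p = 0.0527, for an organelle share of 0.635% in guard cells and 0.497% in subsidiary cells.

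**Figure D1:**
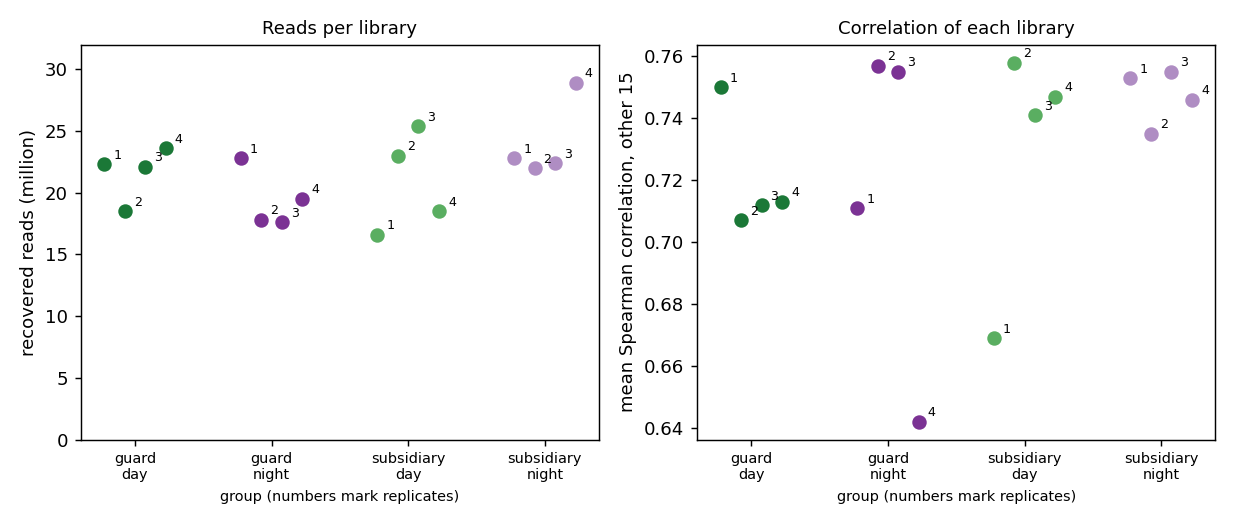
Recovered reads in M (left) and mean Spearman correlation across genes with the other 15 libraries (right) for each of the 16 libraries, by group, with numbers marking replicates. Reads lie between 16.6 and 28.9 M, and the lowest correlations are 0.642 in replicate 4 of guard cells by night and 0.669 in replicate 1 of subsidiary cells by day.

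The comparison of guard with subsidiary cells by day asks which transcripts distinguish the cell types while stomata are lit. Potassium uptake drives stomatal swelling, and 3 of 34 potassium transport genes passed, 1 higher and 2 lower in guard cells. Zm00001d003861, whose description begins with Potassium, was at 3271 ± 999 normalised counts (SD, n = 4) in guard cells and 251 ± 88.2 in subsidiary cells, a log2 fold change of 3.71 ± 0.54 (SE, adjusted p = 0.00175). Another gene described as Potassium, Zm00001d044717, was at 7260 ± 4388 in guard cells and 49159 ± 28294 in subsidiary cells (-2.77 ± 0.42, adjusted p = 0.00219). The MYB gene Zm00001d053124 was higher in guard cells, at 9926 ± 5298 against 391 ± 416 (5.08 ± 0.58, adjusted p = 0.000578) and the CONSTANS-like gene Zm00001d051684 at 8193 ± 1998 against 992 ± 389 (3.12 ± 0.45, adjusted p = 0.00175). The dehydrin Zm00001d033483, of a class known for protection in drying tissue, was at 14047 ± 4301 against 1302 ± 802 (3.59 ± 0.62, adjusted p = 0.0062).

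Further genes higher in guard cells by day were PVR3-like Zm00001d005146 (log2 fold change 6.32), the MYB gene Zm00001d006236 (4.63), Carboxypeptidase Zm00001d047235 (3.83), the glutathione transferase GST7 Zm00001d042104 (3.30), Plasma Zm00001d050214 (3.02), Ubiquitinyl Zm00001d006079 (2.50 ± 0.32) and Alanine--tRNA Zm00001d023741 (2.15). Among starch genes, Glucose-1-phosphate Zm00001d033910 was higher by 2.76. Auxin Zm00001d049295 was higher by 1.83. In subsidiary cells the higher genes were Serine/threonine-protein Zm00001d028245 (-3.11), Glycine-rich Zm00001d045875 (-3.05), the transporter ABC Zm00001d002871 (-2.50), Dihydroflavonol-4-reductase Zm00001d009666 (-2.19), Polycomb Zm00001d024698 (-1.85), Carboxypeptidase Zm00001d005973 (-1.72), the wall polymer gene Cellulose Zm00001d034770 (-1.72), the cell cycle regulator E2F-DP Zm00001d004512 (-1.68) and Serine/threonine-protein Zm00001d035949 (-1.54). The call of Zm00001d004512 ended without subsidiary day replicate 4 (adjusted p = 0.0532), and that of Zm00001d035949 ended without guard day replicate 4 or subsidiary day replicate 2 or 4 (0.0514 to 0.0613).

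Several list members passed by day on less firm ground. Beta-amylase Zm00001d027619, which degrades starch, was higher in guard cells by 2.00 (10360 ± 2396 against 2546 ± 153). That call ended without any 1 of the 8 day libraries (adjusted p 0.0627 to 0.0938). Ribulose Zm00001d048593 was higher by 3.03. This call ended without guard day replicates 1, 3 or 4 or subsidiary day replicates 2, 3 or 4 (0.0701 to 0.0982). The clock list gene CCT Zm00001d012441 was higher by 3.02. Its call ended without any 1 library except guard night replicate 4 and subsidiary day replicate 1 (0.0581 to 0.149). Its fold change was 1.64 in DESeq2 (adjusted p = 0.248) and 1.66 in edgeR (adjusted p = 0.384), and subsidiary day replicate 1, at 789 normalised counts, lay at the guard cell level of 724 ± 118 (SD, n = 4). Histone Zm00001d002601 was higher by 3.91, a call that ended without guard day replicates 1, 3 or 4 or subsidiary day replicates 1 or 4 (0.0558 to 0.0661). Potassium Zm00001d046679 was lower by -1.68, a call lost without guard day replicates 1 to 4, guard night replicate 3, subsidiary day replicates 2 to 4 or subsidiary night replicates 2 or 3 (0.0513 to 0.135). Beta-expansin Zm00001d019560, of a class that loosens walls, was lower by -2.24, a call lost without any 1 library except guard day replicate 3 and guard night replicates 1 and 4 (0.0518 to 0.138).

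As groups, 2 of the 44 photosystem and electron transport genes passed as higher in guard cells by day, Photosystem Zm00001d042178 (7.90 ± 1.66, adjusted p = 0.0209; 6.31 in edgeR) and Photosystem Zm00001d034283 (2.61 ± 0.60, adjusted p = 0.0328), and 7 did so adjusted over the list alone. The list median was 1.52 with 37 members higher (limma's camera, adjusted p = 1.62e-08), and adjusted p = 0.532 with an estimated correlation. The former gene's call ended without guard day replicates 1, 3 or 4 or subsidiary day replicates 1 or 2 (0.0587 to 0.0682), the latter's without guard day replicates 1, 3 or 4 or subsidiary day replicates 1, 2 or 4 (0.0578 to 0.116). Of 32 chlorophyll-binding genes 0 passed over all genes (limma, 1 adjusted over the list alone, Zm00001d018157 at 2.28), with a list median of 1.18 (camera adjusted p = 0.00197; adjusted p = 0.686 with an estimated correlation). Over all genes Zm00001d018157 had an adjusted p of 0.0594 in limma, 0.0494 with a pseudocount of 10, 0.0123 with only the groups compared and 0.00742 in DESeq2. Photosystem transcripts took 0.336 ± 0.105% of reads (SD, n = 4) in guard cells and 0.153 ± 0.0677% in subsidiary cells, and the mesophyll C4 list, genes described as Carbonic or Phosphoenolpyruvate, took 0.0337 ± 0.0096% and 0.0189 ± 0.00975%. That mesophyll list had a median of 1.37 and a mean of 0.48, with 4 of 6 members higher in guard cells (camera adjusted p = 0.437). Without subsidiary day replicate 1 its median was 0.93 and its mean -0.22. First words do not tell which enzyme such a gene encodes, so the list may hold genes that are not particular to mesophyll. The wax synthesis list, meant to hold genes that build the cuticle, was lower in guard cells (median -0.54, camera adjusted p = 0.00197, and 0.289 with an estimated correlation). Here too first words do not tell which protein a gene encodes. In limma 0 of 29 wax genes passed over all genes, and adjusted over the list alone 3 were lower, 3-ketoacyl-CoA Zm00001d027904 (-2.89, limma adjusted p = 0.0554 over all genes), 3-ketoacyl-CoA Zm00001d009354 (-2.43, 0.0668) and CER5 Zm00001d010426 (-2.08, 0.129). DESeq2 called Zm00001d027904 (adjusted p = 0.0069) and Zm00001d009354 (0.00112). Further limma settings called Zm00001d027904 (upper-quartile scaling, a pseudocount of 10, quality weights, a replicate block; adjusted p 0.0329 to 0.0499) and Zm00001d009354 (quality weights, 0.00932). Without both libraries of lowest correlation each of the 3 passed (0.00167 to 0.0477). Potassium transport passed with 1 gene higher and 2 lower of 34, over all genes and adjusted over the list alone, and its list test did not (adjusted p = 0.813).

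In total 505 genes differed between the cell types by day, 356 higher and 149 lower in guard cells, with 4683 genes at an unadjusted p under 0.05. The groups did not overlap for 2944 genes (7.80%, against 2.86% by chance). Without 1 library the count fell to 333 (guard day replicate 2), 244 (guard day replicate 3), 261 (guard day replicate 4) or 234 (subsidiary day replicate 4), or came to 815 (guard night replicate 4). The split was 195 higher and 159 lower without guard day replicate 1, 288 and 53 without subsidiary day replicate 2, and 189 and 45 without subsidiary day replicate 4. Quality weights gave 824 genes, DESeq2 gave 1648, and leaving out both libraries of lowest correlation gave 762 (464 higher, 298 lower). Of the genes named for this comparison 8 were not called by edgeR (adjusted p 0.0528 to 0.384), Zm00001d012441, Zm00001d019560, Zm00001d027619, Zm00001d034283, Zm00001d042178, Zm00001d045875, Zm00001d046679 and Zm00001d048593.

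By night the same comparison asks which differences persist in the dark. Few genes passed, and those that did were mostly without a description. Zm00001d021153 was at 248 ± 194 normalised counts (SD, n = 4) in guard cells against 7.93 ± 3.03 in subsidiary cells (4.50 ± 0.67, adjusted p = 0.0322), and Zm00001d046676 was at 560 ± 292 against 4058 ± 1061 (-3.03 ± 0.46, adjusted p = 0.0322). Carboxypeptidase Zm00001d047235 was at 920 ± 431 against 107 ± 69.1 (3.09 ± 0.53, adjusted p = 0.0429), and PRA1 Zm00001d015125, of a class in vesicle traffic, at 398 ± 274 against 2297 ± 782 (-2.71 ± 0.44, adjusted p = 0.0429). The other called genes, chosen after their values were seen where the rule did not take them, were Zm00001d026355 (3.62), Zm00001d030331 (3.55), Zm00001d024568 (3.33), Zm00001d044739 (3.17) and Zm00001d051158 (1.88) as higher, and Zm00001d029794 (-3.20) and Zm00001d032919 (-2.94) as lower.

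The 3 potassium genes called by day had the same sign by night but did not pass in limma. Potassium Zm00001d003861 had a log2 fold change of 2.84 ± 0.54 (adjusted p = 0.0617), Potassium Zm00001d044717 had -1.86 ± 0.42 (adjusted p = 0.103) and Potassium Zm00001d046679 had -1.73 (adjusted p = 0.124). The sugar transporter Bidirectional Zm00001d038226 had -3.48, with 2791 ± 2060 against 21036 ± 4173 normalised counts (SD, n = 4; adjusted p = 0.059). Aquaporin Zm00001d005421 had -2.75 by night (adjusted p = 0.0698) and the opposite sign by day, 0.56 ± 0.54 (adjusted p = 0.755). Other settings called several of these by night. Quantile normalization, upper-quartile scaling, a pseudocount of 10, quality weights, DESeq2 and leaving out both libraries of lowest correlation called Zm00001d003861 (adjusted p 3.05e-05 to 0.0475) and Zm00001d038226 (0.000625 to 0.0438). Quality weights (0.00919), DESeq2 (0.0062) and leaving out both libraries (0.0377) called Zm00001d005421. Quality weights (0.0403) and DESeq2 (0.00449) called Zm00001d044717, and DESeq2 called Zm00001d046679 (0.00972). As a group the 167 cytosolic ribosomal protein genes were lower in guard cells by night, with a median of -0.62 and 125 members lower (camera adjusted p = 0.000884; adjusted p = 0.662 with an estimated correlation), while 0 members passed, over all genes or adjusted over the list alone (limma). Without both libraries of lowest correlation the list's adjusted p was 0.523, and guard night replicate 4, where ribosomal genes were low, is 1 of them.

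Altogether 11 genes differed by night, 7 higher and 4 lower in guard cells, with 3237 at an unadjusted p under 0.05. Non-overlapping groups were found for 2192 genes (5.81%, against 2.86% by chance). Each of the 11 calls rests on single libraries. The count was 0 without guard day replicate 2 or 4, guard night replicate 3 or subsidiary night replicate 1 or 2 (limma). It was 2 without subsidiary night replicate 3, 4 without guard day replicate 3, guard night replicate 1, subsidiary day replicate 3 or subsidiary night replicate 4, and 5 without guard day replicate 1 or subsidiary day replicate 2. It came to 45 without subsidiary day replicate 1, to 65 without guard night replicate 2 and to 114 without guard night replicate 4. The highest adjusted p of a called gene with 1 library left out was 0.181, for Zm00001d051158 without subsidiary night replicate 2. The split between directions moved as well, to 7 higher and 58 lower without guard night replicate 2, 100 and 14 without guard night replicate 4, 24 and 21 without subsidiary day replicate 1, and 1 and 3 in a fit of only the groups compared. Without both libraries of lowest correlation it was 142 and 28, with a pseudocount of 10 it was 13 and 15, and with a replicate block it was 4 and 6. The block ended the limma calls of Zm00001d047235 (adjusted p = 0.0749), Zm00001d015125 (0.0673), Zm00001d051158 (0.0749) and Zm00001d024568 (0.058). DESeq2 called 615 genes, and edgeR 2, Zm00001d044739 and Zm00001d021153. The fit of only the groups compared called 0 of the 11 genes (limma, adjusted p 0.128 to 0.159). Genes called at both times were 5 as higher in guard cells (Zm00001d051158, Zm00001d047235, Zm00001d044739, Zm00001d030331 and Zm00001d026355; 0.066 expected from independent lists) and 3 as lower (Zm00001d046676, Zm00001d029794 and Zm00001d015125; 0.0158 expected). Both comparisons take the spread of each gene from the same 16 libraries, so these expected numbers are only a rough reference. The Pearson correlation of the day and night differences was 0.17 across all genes, which are not independent replicates. Of the 356 genes called as higher in guard cells by day 297 had the same sign by night, as had 130 of the 149 called as lower.

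Day against night in guard cells asks which transcripts differ between 2 h after lights on and 2 h after lights off. Light, temperature and time of day change together in this growth cycle, so their effects cannot be told apart. Light-harvesting transcripts rose by day. The chlorophyll-binding gene Zm00001d021784 went from 92.3 ± 36.5 normalised counts by night to 3966 ± 603 by day (SD, n = 4; log2 fold change 5.48 ± 0.45, adjusted p = 3.18e-06), and Photosystem Zm00001d018797 from 121 ± 148 to 7356 ± 1169 (6.86 ± 0.66, adjusted p = 1.75e-05). Aquaporin Zm00001d005421, of the water channel family, rose from 103 ± 100 to 2055 ± 743 (4.67 ± 0.54, adjusted p = 0.000146), and Potassium Zm00001d044717 from 797 ± 106 to 7260 ± 4388 (3.02 ± 0.42, adjusted p = 0.000739). The gene described as Cell, Zm00001d012900, fell from 2993 ± 3076 by night to 34.7 ± 18.8 by day (-5.91 ± 0.78, adjusted p = 0.000517).

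Other genes that rose in guard cells by day were Chlorophyll Zm00001d009589 (8.28), PVR3-like Zm00001d005146 (7.74), GST7 Zm00001d042104 (3.91), Glucose-6-phosphate Zm00001d020771 (3.55), Transmembrane Zm00001d000428 (3.28), Leaf Zm00001d006184 (2.51) and Auxin Zm00001d049295 (2.20). Plasma Zm00001d050214 rose by 1.81, a call that ended without guard day replicates 1, 2 or 4 or guard night replicates 3 or 4 (adjusted p 0.0672 to 0.108). Genes that fell by day were VQ Zm00001d046728 (-2.94), the cell cycle gene Anaphase-promoting Zm00001d038881 (-3.76), the sterol pathway gene Squalene Zm00001d047998 (-3.91) and UDP-glucose Zm00001d013245 (-2.82). The VQ call ended without guard night replicate 3 (0.0525), and that of Zm00001d038881 without guard day replicates 2 or 3 or guard night replicates 2 or 3 (0.0616 to 0.0745). That of Zm00001d047998 ended without guard day replicates 2 or 4 or guard night replicates 1, 2 or 4 (0.0508 to 0.109), and that of Zm00001d013245 ended without any 1 library except guard night replicate 3 and subsidiary day replicate 1 (0.051 to 0.151). Heat shock and chaperone genes went both ways in guard cells, with 2 higher by day, Heat Zm00001d012420 (2.17) and Heat Zm00001d028630 (2.63), and 1 lower, Hsp20/alpha Zm00001d021634 (-3.26), of 45, over all genes and adjusted over the list alone. The first of these calls ended without guard day replicates 3 or 4 or guard night replicate 2 (0.0653 to 0.102), and that of Zm00001d028630 without guard day replicates 1, 3 or 4, guard night replicates 1 to 3, subsidiary day replicate 4 or subsidiary night replicates 1, 3 or 4 (0.0561 to 0.154).

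In guard cells 11 of 32 chlorophyll-binding genes rose by day, 20 adjusted over the list alone, including Zm00001d033136 (5.65) and Zm00001d033132 (5.61), and the list median was 3.66 (camera adjusted p = 1.21e-24; adjusted p = 0.0179 with an estimated correlation). Chlorophyll-binding transcripts took 0.223 ± 0.0763% of reads by day and 0.0273 ± 0.0182% by night (SD, n = 4). Some members of this family may be similar copies, which was not tested, so single genes are uncertain where reads are shared. Of the 44 photosystem and electron transport genes 3 rose, Zm00001d018797, Zm00001d034283 (2.79) and PGR5 Zm00001d031850 (5.61, and 4.49 in edgeR), and 13 adjusted over the list alone, with a median of 1.85 (camera adjusted p = 4.06e-14; adjusted p = 0.0896 with an estimated correlation). The call of Zm00001d034283 ended without guard day replicates 1 or 3 or guard night replicates 1 to 3 (0.0616 to 0.115), and that of Zm00001d031850 without any 1 library except guard night replicate 1, subsidiary day replicate 1 and subsidiary night replicates 2 and 3 (0.0514 to 0.143). Guard night replicate 4, where photosystem genes were low, is in the night group of this comparison. Clock and photoperiod genes rose as a list (median 0.71, camera adjusted p = 0.00564; adjusted p = 0.0418 with an estimated correlation). Of its 19 members 2 passed, C2C2-CO-like Zm00001d046925 (7697 ± 2692 by day, 971 ± 557 by night, 3.22) and Constans1 Zm00001d045735 (2.07), and 3 adjusted over the list alone, with C2C2-CO-like Zm00001d051684 (1.47) as the other. Constans1's call ended without guard day replicates 1 or 4 or any 1 of the guard night libraries (0.053 to 0.111).

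Vacuolar proton pump genes, which acidify the vacuole, were higher by day in guard cells as a list (median 0.82, 15 of 18 members, camera adjusted p = 0.033; adjusted p = 0.0947 with an estimated correlation, and 0.0581 without both libraries of lowest correlation). None of the 18 passed over all genes in limma, and 1 did adjusted over the list alone, V-type Zm00001d028436 (2269 ± 515 normalised counts by day and 909 ± 376 by night, SD, n = 4; limma adjusted p = 0.0691 over all genes, DESeq2 adjusted p = 0.0163). Mesophyll C4 genes were also higher as a list (median 0.67, 5 of 6 members, camera adjusted p = 0.033; adjusted p = 0.493 with an estimated correlation), with 0 called over all genes (limma) and 2 adjusted over the list alone, Carbonic Zm00001d005920 (3.18) and Carbonic Zm00001d044096 (1.92). Over all genes Zm00001d005920 had an adjusted p of 0.0992 in limma, 0.019 with only the groups compared, 0.0307 without both libraries of lowest correlation and 0.0038 in DESeq2. Cytosolic ribosomal protein genes were lower by day (median -0.38, camera adjusted p = 0.0208; adjusted p = 0.719 with an estimated correlation), with 2 of 167 called, 40S Zm00001d037886 (-3.08) and 40S Zm00001d037884 (-2.89), also adjusted over the list alone. Their calls ended without guard day replicates 2 or 4 or guard night replicates 1 to 3, and for Zm00001d037884 also without subsidiary day replicates 2 to 4 or any 1 of the subsidiary night libraries (0.0517 to 0.121 over both genes). Guard night replicate 4, in the night group here, had low ribosomal values (median log2 of -1.54 against the rest of its group). Without both libraries of lowest correlation the ribosomal list's camera adjusted p was 6.7e-08 with the preset correlation.

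In all 327 genes changed between day and night in guard cells, 282 higher and 45 lower by day, with 3802 at an unadjusted p under 0.05, and 2155 genes (5.71%, against 2.86% by chance) had groups that did not overlap. Upper-quartile scaling took the median of all genes from -0.01 to -0.13 here and from 0.03 to -0.12 in the interaction. Without guard day replicate 1 the count was 194, and without guard day replicate 3 it was 182; edgeR gave 196 and DESeq2 1099. DESeq2 also moved the split to 734 higher and 365 lower, leaving out both libraries of lowest correlation moved it to 299 and 156, and leaving out guard night replicate 4 alone to 242 and 105. Of the genes named for this comparison 8 were not called by edgeR (adjusted p 0.0605 to 0.158), Zm00001d003006, Zm00001d013245, Zm00001d028630, Zm00001d031850, Zm00001d037884, Zm00001d037886, Zm00001d038881 and Zm00001d047998. A fit of only the groups compared did not call 11 of the named genes (adjusted p 0.073 to 0.232), among them Hsp20/alpha Zm00001d021634 (0.0791) and VQ Zm00001d046728 (0.0846).

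**Figure D2:**
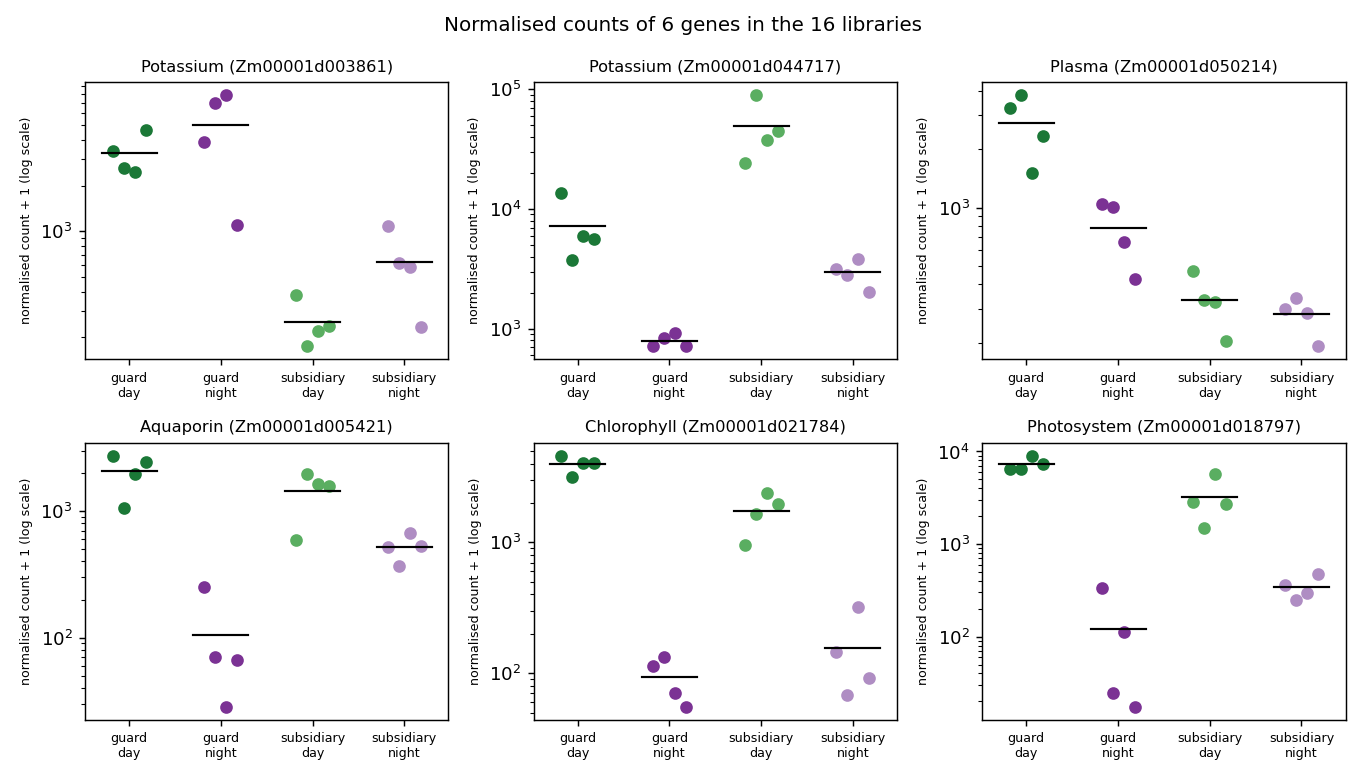
Normalised counts + 1 (log scale) of 6 genes in the 16 libraries, by group; points are libraries and lines are group means. Potassium Zm00001d044717 has its highest mean in subsidiary cells by day (49159) and Potassium Zm00001d003861 in guard cells by night (4978), while Aquaporin Zm00001d005421, Chlorophyll Zm00001d021784 and Photosystem Zm00001d018797 have higher means by day than by night in both cell types.

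Day against night in subsidiary cells asks the same of the neighbouring cells. Potassium Zm00001d044717 rose from 2953 ± 760 normalised counts by night to 49159 ± 28294 by day (SD, n = 4; log2 fold change 3.93 ± 0.42, adjusted p = 5.42e-05), the chlorophyll-binding gene Zm00001d039040 from 67.4 ± 60.4 to 3117 ± 2612 (5.99 ± 0.84, adjusted p = 0.000765), and E2F-DP Zm00001d004512 from 511 ± 158 to 4585 ± 1123 (3.17 ± 0.33, adjusted p = 4.61e-05). Among genes of histones, which package DNA, some fell by day and 1 rose, Zm00001d021300. Histone Zm00001d034479 went from 1544 ± 533 by night to 90.5 ± 18.2 (-4.01 ± 0.56, adjusted p = 0.000671), and Histone Zm00001d002601 from 5159 ± 615 to 151 ± 94.5 (-5.46 ± 0.84, adjusted p = 0.00155). The small heat shock gene Hsp20/alpha Zm00001d021634 fell from 1330 ± 229 to 99.4 ± 69.6 (-3.95 ± 0.61, adjusted p = 0.00163).

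Also higher by day in subsidiary cells were Anther-specific Zm00001d018791 (5.36), Guanosine Zm00001d010251 (4.09), Leaf Zm00001d006184 (3.19), the lipid precursor gene Glycerol-3-phosphate Zm00001d024967 (3.15), Nucleotide-sugar Zm00001d012153 (3.07) and HESB-like Zm00001d008405 (2.77). Lower by day were Histone Zm00001d025335 (-5.77), Histone Zm00001d013066 (-5.71), VQ Zm00001d046728 (-4.85), Peroxidase Zm00001d037550 (-4.77), the MYB gene Zm00001d006236 (-4.11), GTPase Zm00001d019836 (-3.64) and Phosphoserine Zm00001d048794 (-3.19). The light receptor gene Phytochrome Zm00001d034038 was lower by day by -1.94, a call that ended without subsidiary day replicates 1, 2 or 4 or any 1 of the subsidiary night libraries (adjusted p 0.0515 to 0.14). Starch Zm00001d019479 was lower by -1.93, which ended without any 1 of the 8 subsidiary cell libraries (0.0512 to 0.0945).

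Of the 105 histone and cyclin genes 11 fell by day in subsidiary cells and 2 rose, Histone Zm00001d021300 (4.26) and Cyclin Zm00001d008221 (1.92), with 16 and 3 adjusted over the list alone. The list median was -0.75 with 69 members lower (camera adjusted p = 3.87e-05; adjusted p = 0.207 with an estimated correlation), and its share of reads was 0.0774 ± 0.0251% by day and 0.251 ± 0.0363% by night (SD, n = 4). The cyclin's call ended without subsidiary day replicates 2 to 4 or subsidiary night replicates 1 or 3 (0.0507 to 0.107). Some histone genes may be similar copies, which was not tested, so reads may be shared between them. Cytosolic ribosomal protein genes fell as a list, with a median of -0.98 and 144 of 167 members lower (camera adjusted p = 2.55e-11; adjusted p = 0.207 with an estimated correlation), with 2 called, 40S Zm00001d019147 (-3.48) and 60S Zm00001d049790 (-2.07), and 6 adjusted over the list alone. Their share of reads was 0.16 ± 0.0138% by day and 0.359 ± 0.0503% by night. The call of Zm00001d049790 ended without guard day replicates 1 or 3, guard night replicate 3, subsidiary day replicates 2 to 4 or any 1 of the subsidiary night libraries (0.0533 to 0.136).

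Chlorophyll-binding genes rose by day in subsidiary cells too, 5 of 32 over all genes and 17 adjusted over the list alone with 1 lower, at a median of 2.68 (camera adjusted p = 1.29e-11; adjusted p = 0.207 with an estimated correlation). Besides Zm00001d039040 these were Zm00001d021906 (5.62), Zm00001d033136 (3.75), Zm00001d021784 (3.65) and Zm00001d033132 (3.46). Calls of Zm00001d033136 and Zm00001d033132 ended without subsidiary day replicates 3 or 4 or subsidiary night replicates 2 or 3, and the latter also without subsidiary night replicate 1 (0.0677 to 0.124). In the photosystem list 1 of 44 genes rose, Zm00001d018797 (3.09), whose call ended without subsidiary day replicates 1, 3 or 4 or subsidiary night replicates 1 to 3 (0.0537 to 0.0894), and 2 did adjusted over the list alone, the other being Ferredoxin Zm00001d045575 (2.13; over all genes adjusted p = 0.101 in limma, 0.0243 with quality weights and 0.00611 in DESeq2). That list's median was 0.36 (camera adjusted p = 0.105, and 0.000297 without both libraries of lowest correlation, of which subsidiary day replicate 1 had low photosystem values). Wax synthesis genes were higher by day as a list (median 0.42, camera adjusted p = 0.0195; adjusted p = 0.214 with an estimated correlation), with 0 of 29 called over all genes or adjusted over the list alone (limma). Among 45 heat shock and chaperone genes 1 rose, DnaJ Zm00001d012242 (3.75), and 3 fell, Heat Zm00001d043536 (-4.37), Hsp20/alpha Zm00001d021634 and Heat Zm00001d047214 (-3.21), with 3 and 4 adjusted over the list alone. The call of Zm00001d043536 was lost in edgeR (-3.12, adjusted p = 0.128). The call of Zm00001d047214 ended without subsidiary day replicates 1, 3 or 4 or subsidiary night replicates 1 to 3 (0.0602 to 0.142).

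In subsidiary cells 461 genes changed between day and night, 254 higher and 207 lower by day, with 4242 at an unadjusted p under 0.05. Groups did not overlap for 3337 genes (8.84%, against 2.86% by chance). The count was 259 without subsidiary day replicate 4 and 235, 246, 273 and 292 without subsidiary night replicates 1, 2, 3 and 4. Quality weights gave 959 genes and DESeq2 1353. Of the genes named for this comparison 7 were not called by edgeR (adjusted p 0.0503 to 0.128), Zm00001d008221, Zm00001d019563, Zm00001d033132, Zm00001d034038, Zm00001d043536, Zm00001d047214 and Zm00001d049790.

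Day and night lists of the cell types overlapped. Among genes higher by day 93 were called in both cell types (1.90 expected from independent lists), and among genes lower by day 16 were (0.247 expected), with 0 called in opposite directions in limma. Of the 282 genes higher by day in guard cells 249 had the same sign in subsidiary cells, and the Pearson correlation of the day minus night differences was 0.21 (Spearman 0.18) across all genes. The groups compared share no libraries, but the spread of each gene was estimated over all 16 libraries. Calls in the cell types are thus not independent, and the expected numbers are only a rough reference.

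The interaction asks whether the day to night change itself differs between the cell types. No single gene passed, as limma called 0 genes (2533 at an unadjusted p under 0.05, smallest adjusted p = 0.0659), edgeR 1 and DESeq2 153. Without 1 library limma called 1 (guard night replicate 1 or 2, or subsidiary day replicate 1), 2 (guard night replicate 3) or 6 (subsidiary day replicate 2). Heat Zm00001d043536 had a difference of 5.85 ± 1.21 (adjusted p = 0.247), with 380 ± 114 normalised counts by day and 183 ± 149 by night in guard cells, and 85.8 ± 126 and 745 ± 138 in subsidiary cells (SD, n = 4). Histone Zm00001d002601 had 4.99 ± 1.18 (adjusted p = 0.351, and 0.0326 in DESeq2) and Photosystem Zm00001d018797 had 3.77 ± 0.94 (adjusted p = 0.373).

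As lists, photosystem genes had a larger day minus night difference in guard than in subsidiary cells, with a median of 1.47 and 37 of 44 members positive (camera adjusted p = 2.18e-05), as had chlorophyll-binding genes (1.43, adjusted p = 0.00424). Cytosolic ribosomal genes (0.65, adjusted p = 0.00424) and histone and cyclin genes (0.67, adjusted p = 0.014) had positive medians too. With the preset correlation ribosomal genes passed as lower by day in both cell types, histone and cyclin genes only in subsidiary cells. In guard cells the histone and cyclin list had a median of -0.31 (camera adjusted p = 0.483, and 0.00272 without both libraries of lowest correlation). Each of these 4 lists had an adjusted p of 0.654 with an estimated correlation. Without guard night replicate 4 none of the 4 passed (adjusted p 0.0668 to 0.715). With other single libraries left out at least 1 list was lost without guard day replicate 1 (highest adjusted p = 0.0676), guard day replicate 4 (0.0717) or subsidiary day replicate 2 (0.141). Over all genes 0 members of these lists passed (limma). Adjusted over the list alone these were 1 chlorophyll-binding gene, Zm00001d021763 (4.01), 2 photosystem genes, Zm00001d018797 and Zm00001d042178 (8.69), 0 of 167 ribosomal genes, and 3 histone genes, Zm00001d002601, Zm00001d009350 (7.21) and Zm00001d034479 (3.15).

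Aquaporins are the water channels named in the series title. In guard cells 4 of 22 measured members rose by day, over all genes and adjusted over the list alone: Zm00001d005421, Zm00001d051174 (802 ± 425 normalised counts by day and 34.4 ± 21.3 by night, SD, n = 4; 4.58 ± 0.77, adjusted p = 0.00492), Zm00001d003006 (6.57 ± 1.39, adjusted p = 0.0255) and Zm00001d051872 (3.76 ± 0.87, adjusted p = 0.0448). The list rose with a median of 1.05, 17 members being higher by day (camera adjusted p = 6.98e-05; adjusted p = 0.0418 with an estimated correlation). In subsidiary cells 1 of 22 rose, Zm00001d019563, from 106 ± 117 by night to 3373 ± 3039 by day (5.99 ± 1.32, adjusted p = 0.0282), and 3 did adjusted over the list alone, with Zm00001d051174 (2.95, adjusted p = 0.0743 over all genes) and Zm00001d017526 (2.17, 0.135). Over all genes Zm00001d051174 passed there with quality weights (adjusted p = 0.00859), edgeR (0.0351), DESeq2 (6.07e-05) and without both libraries of lowest correlation (0.0055). Zm00001d017526 passed with quality weights (0.022), DESeq2 (0.00946) and without both libraries (0.0398), while Zm00001d019563 was lost in edgeR (0.0788). The list median there was 0.71 (camera adjusted p = 0.0207; adjusted p = 0.214 with an estimated correlation). Between the cell types 0 of 22 passed by day or by night in limma, with 1 each adjusted over the list alone, Zm00001d003006 by day (4.94, adjusted p = 0.0929 over all genes) and Zm00001d005421 by night (-2.75, 0.0698). Over all genes Zm00001d003006 passed by day with a pseudocount of 10 (adjusted p = 0.0262), and Zm00001d005421 by night with quality weights (0.00919), DESeq2 (0.0062) and without both libraries of lowest correlation (0.0377). The day list had a median of -0.22 and a mean of 0.02, of opposite sign (adjusted p = 0.92), and the night list a median of -0.39 (adjusted p = 0.353). The difference of the day to night changes was 3.31 ± 0.77 for Zm00001d005421 (adjusted p = 0.344), and the list's own interaction test gave an adjusted p of 0.459.

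Some aquaporin calls rest on few libraries and their reads may be shared between similar copies. In guard cells the call of Zm00001d003006 ended without guard day replicates 1 to 3 or guard night replicates 1 to 3 (adjusted p 0.0524 to 0.0968), and that of Zm00001d051872 without guard day replicates 1, 3 or 4, any 1 of the guard night libraries, subsidiary day replicates 2 or 4 or subsidiary night replicates 1 or 3 (0.0566 to 0.166). In other settings Zm00001d003006 was lost in edgeR (0.0615) and with a pseudocount of 0.1 (0.0509), and Zm00001d051872 with a pseudocount of 0.1, upper-quartile scaling, a replicate block (0.055 to 0.0654) and without both libraries of lowest correlation (0.0772). The subsidiary cell call of Zm00001d019563 ended without subsidiary day replicates 1, 3 or 4 or subsidiary night replicates 1 or 2 (0.0577 to 0.0975). Aquaporin transcripts took 0.0687 ± 0.0232% of reads in guard cells by day, 0.0456 ± 0.0217% by night, 0.0803 ± 0.0218% in subsidiary cells by day and 0.0507 ± 0.0108% by night (SD, n = 4).

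**Figure D3:**
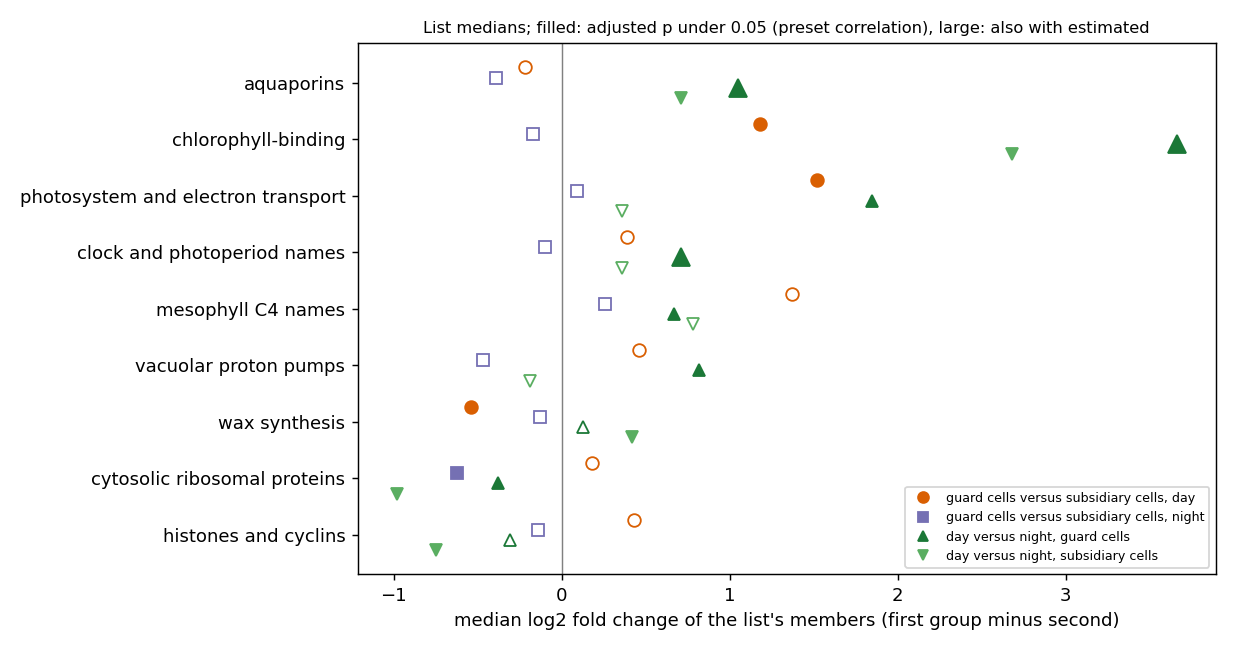
Median log2 fold change of the members of 9 gene lists in the 4 comparisons; filled symbols mark a camera adjusted p under 0.05 with the preset correlation, and large symbols mark lists that also pass with an estimated correlation. The chlorophyll-binding list has medians of 3.66 in guard cells and 2.68 in subsidiary cells for day against night, and 3 lists in guard cells, chlorophyll-binding, aquaporins and clock, pass with both correlations.

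The remaining lists passed in none of the 5 comparisons with the preset correlation. Their smallest adjusted p in any comparison was 0.238 for starch turnover, 0.262 for plasma membrane names and for trehalose metabolism, 0.285 for abscisic acid names, 0.312 for benzoxazinoid and pathogen defence, 0.319 for organelle identifiers, 0.353 for the Calvin cycle and for dehydrins and late embryogenesis, 0.365 for bundle sheath names, 0.451 for photoreceptors, 0.459 for vascular names, 0.472 for cell wall enzymes, 0.477 for sugar transporters, 0.527 for potassium transport and 0.534 for tubulins and actins. It was 0.513 for auxin response, TIFY repressors, chloride channels and expansins, and 0.607 for heat shock and chaperones and for peroxidases.

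The authors' deposited table, from their own DESeq2 run, calls 1657 genes between the cell types by day, 616 by night, 1103 between day and night in guard cells and 1347 in subsidiary cells at an adjusted p under 0.05. Of these, 498, 11, 320 and 457 were also called here by limma, and each of these shared genes had the same direction as in the authors' deposited table.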

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

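The tests of causes in this part were chosen after the results they measure had been seen.

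Within groups of 4 libraries, the highest or lowest value of a gene was taken as far from the others when its gap to the nearest exceeded the 95% critical share of the group's range. Of 404 groups from 101 named genes 29 passed (7.18%), where chance gives about 1 in 20, and 8 of them lay in guard night replicate 4, the library of lowest correlation. Those 8 shares were 0.958 (Zm00001d006079), 0.935 (Zm00001d045735), 0.931 (Zm00001d006236), 0.891 (Zm00001d019147), 0.865 (Zm00001d013066), 0.856 (Zm00001d049790), 0.853 (Zm00001d044096) and 0.851 (Zm00001d030331). In subsidiary day libraries they were 0.943 (Zm00001d004512), 0.888 (Zm00001d029794) and 0.845 (Zm00001d032919) in replicate 2, and 0.916 (Zm00001d013245), 0.875 (Zm00001d013066) and 0.861 (Zm00001d009354) in replicate 1.

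In guard day libraries the shares were 0.983 (Zm00001d048593) and 0.866 (Zm00001d013245) in replicate 2, 0.887 (Zm00001d027619) and 0.83 (Zm00001d021906) in replicate 1, and 0.856 (Zm00001d021300) in replicate 3. The other guard night libraries gave 0.925 (Zm00001d033132, replicate 1) and 0.902 (Zm00001d028630, replicate 3). Subsidiary night libraries gave 0.84 (Zm00001d005146) and 0.861 (Zm00001d034479) in replicate 1, and 0.849 (Zm00001d012420), 0.882 (Zm00001d034770) and 0.86 (Zm00001d047214) in replicate 2. Replicate 3 gave 0.888 (Zm00001d020771) and 0.833 (Zm00001d021906, listed at 0 there), and replicate 4 gave 0.845 (Zm00001d019836). Among library measures, subsidiary night replicate 4 had the most reads of its group (28.9 M, share 0.884), and guard day replicate 1 stood apart in mean correlation (0.75, share 0.86).

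Between the cell types 4 lists differed in their day minus night change, by limma's camera on the interaction. Adjusted p was 2.18e-05 for photosystem, 0.00424 for chlorophyll-binding, 0.00424 for cytosolic ribosomal and 0.014 for histone and cyclin genes, and 0.654 for each of the 4 with an estimated correlation, so the lists pass only with the preset correlation. Without guard night replicate 4 and subsidiary day replicate 1 together, 0 of the 4 lists passed. Among 15 other pairs 10 kept all 4 and 1 kept none, so the pair test by itself does not decide. The 1 other pair that kept none was guard night replicate 4 with subsidiary day replicate 2. Without subsidiary day replicate 1 alone, and without it and guard night replicate 1, 2 or 3, all 4 lists passed. This argues against subsidiary day replicate 1 as a cause by itself. Without guard night replicate 4 alone, a test chosen after the table of left-out libraries was seen, 0 of 4 passed, against 2 to 4 without each of the 15 others. That library is a candidate cause of these differences, and a true difference between the cell types stays open.

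The photosystem list was higher in guard than in subsidiary cells by day, with a median of 1.52 (camera adjusted p = 1.62e-08 with the preset correlation, and adjusted p = 0.532 with an estimated correlation). Without the subsidiary day library of lowest correlation its median was 1.12, with 37 of 44 members higher (camera adjusted p = 4.35e-06 with the preset correlation). The remaining shift argues against that library as the whole cause of the list's median. The test without it was not run with an estimated correlation, so it does not show that the list differs. Whether RNA of mesophyll cells caught with the guard cells contributes is undecided, since the mesophyll C4 list had a median of 1.37 and a mean of 0.48, but 0.93 and -0.22 without that library (photosystem median 1.12). Members of the mesophyll C4 list went both ways, 4 of 6 higher (camera adjusted p = 0.437). The most abundant, Zm00001d044096, was at 3999 ± 1328 against 1595 ± 906 normalised counts (SD, n = 4). Laser selection is meant to leave mesophyll cells out. The list rests on first words of descriptions, so its genes may not be particular to mesophyll, and it cannot settle the question. A larger photosynthetic program in guard cells was not tested apart from mesophyll RNA and stays open too.

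Fewer genes were called between the cell types by night (11) than by day (505). Spread from the guard night library of lowest correlation may account for part of this, since 114 genes were called by night without it. That stays under 234, the lowest day count with 1 library left out, and under the 815 genes called by day in the same fit. Both argue against it as the whole cause. The interaction asks gene by gene whether the difference between the cell types changes with time. There limma called 0 genes (smallest adjusted p = 0.0659), edgeR 1 and DESeq2 153. In limma's simulated check it recovered 4 of 66 genes changed 16-fold, so 0 calls cannot exclude such a change. A smaller difference between the cell types in the dark thus stays open.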

How the results depend on the processing

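TMM scaling, edgeR, DESeq2 and leaving out both libraries of lowest correlation were chosen after seeing the data. In each setting below, genes are counted for guard against subsidiary cells by day (505 in the report) and by night (11), for day against night in guard cells (327) and in subsidiary cells (461), and for the interaction (0). The cause of each change was not tested unless given.

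Among counts beyond 1.5 times those of the report, night came to 36 with quantile normalization, 36 with upper-quartile scaling and 28 with a pseudocount of 10, which gave 4 for the interaction. Quality weights gave 824 by day, 185 by night and 959 in subsidiary cells. A fit of only the groups compared, with fewer libraries, gave 4 by night (0 of them among the 11) and 203 in guard cells (196 higher, 7 lower). At an adjusted p under 0.01, which can only lower counts, there were 139 (113 higher, 26 lower), 0 (limma), 125 and 175. edgeR gave 2 by night, 196 in guard cells and 1 for the interaction. DESeq2 gave 1648 (996 higher, 652 lower), 615, 1099, 1353 and 153, and shared 498, 11, 320 and 457 with the report. Without both libraries of lowest correlation there were 762 by day (464 higher, 298 lower) and 170 by night. TMM scaling, no filter, the stricter filter, a pseudocount of 0.1 and a minimum log2 fold change of 1 kept each count within 1.5 times. That minimum could remove no gene, since every called gene had an absolute log2 fold change of at least 1.19.

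Leaving out 1 library at a time gave 234 to 815 genes by day, 0 to 114 by night, 182 to 383 in guard cells, 235 to 645 in subsidiary cells and 0 to 6 for the interaction. With the replicate number as a block the counts were 465, 10, 305, 386 and 0. Deviations from the group means were correlated across genes between libraries of different groups. For 24 pairs with the same number the correlation was -0.061 to 0.079 (median 0.002, against -0.002 for other numbers). No pairing by number was thus seen, but values this low cannot show that such samples were collected apart, and the labels leave it open.

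Of 132 gene results, 107 of them called, 0 reversed under any setting. Calls lost were 7 with quantile normalization, 4 with upper-quartile scaling, 1 with TMM, 0 with either filter, 8 with a pseudocount of 0.1, 1 with quality weights, 10 with the block, 25 with only the groups compared, 32 with edgeR, 1 with DESeq2 and 8 without both libraries. Leaving out 1 library ended 44 calls at least once and left 63 in place throughout. Among lists, an estimated correlation left 3 calls, chlorophyll-binding, aquaporins and clock genes in guard cells between day and night. Quantile normalization and the block kept the list calls of the report. Leaving out both libraries of lowest correlation ended 6 list calls, ribosomal by night (adjusted p = 0.523), vacuolar pumps in guard cells (0.0581) and the 4 of the interaction (0.115 to 0.823). It added 6: photosystem by night (0.000571) and in subsidiary cells (0.000297), histones by day (0.00774) and in guard cells (0.00272), and mesophyll C4 (0.023) and organelle identifiers (0.0189) in subsidiary cells.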

Other observations

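The family tests and the regroupings of libraries in this part were chosen after the results had been seen.

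The shares of reads below were not tested, and the tests of their lists did not pass in any comparison. Sugar transporters took 0.0785 ± 0.0176% of reads in guard cells by day and 0.0877 ± 0.0383% by night, against 0.148 ± 0.0363% and 0.195 ± 0.00472% in subsidiary cells (SD, n = 4). Their list medians between the cell types were -0.20 by day and -0.24 by night, with 14 and 13 of 30 members higher in guard cells. A share can be led by 1 abundant member, such as Zm00001d038226, whose night counts are given above. Trehalose metabolism took 0.0209 ± 0.00476% and 0.0286 ± 0.00508% in guard cells, against 0.0124 ± 0.00194% and 0.0147 ± 0.00149%. Dehydrins and late embryogenesis genes took 0.07 ± 0.0247% and 0.0316 ± 0.0201% in guard cells, against 0.00821 ± 0.00385% and 0.0113 ± 0.00425%. By day 1 gene, Zm00001d033483, was at 14047 ± 4301 against 1302 ± 802 normalised counts, while 7 of the 10 members were lower in guard cells (median -0.30, mean 0.06). Heat shock and chaperone genes took 0.0742 ± 0.0245% and 0.072 ± 0.0148% in guard cells, against 0.0614 ± 0.00871% and 0.0795 ± 0.0102%.

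Glycine-rich genes, many of which encode wall or RNA-binding proteins, were lower by day in subsidiary cells as a family of 10, with a median of -1.75 and 9 members lower (camera adjusted p = 0.000215; adjusted p = 0.354 with an estimated correlation). By night they were lower in guard than in subsidiary cells (-0.98, adjusted p = 0.0319; 0.696 with an estimated correlation). Thioredoxin genes, some of which pass light-driven redox signals to enzymes, had a larger day minus night difference in guard cells. Their median was 1.13, with 13 of 16 members positive (camera adjusted p = 0.0153, and 0.886 with an estimated correlation). This family was not tested without guard night replicate 4, without which 0 of the 4 interaction lists passed.

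Each count of called genes was compared with those from all 35 splits of the 8 libraries into 4 and 4. For guard against subsidiary cells by day 1 of 35 splits, the real one, gave as many as 505 genes, and the highest other gave 9. By night it was 1 of 35, with 11 genes against at most 3. Between day and night it was 1 of 35 in guard cells (327 against at most 4) and 1 of 35 in subsidiary cells (461 against at most 1). The real split gave the most genes in each of these 4 comparisons, and 1 of 35 is the smallest share such splits can give. That share was not adjusted over the 4 counts. Splits that mix the real groups carry any true difference as spread, which lowers their counts. The night count also fell to 0 without some single libraries, so chance is not excluded for it. For the interaction the real count was 0 (limma; 2533 genes at an unadjusted p under 0.05, edgeR 1, DESeq2 153), so each of the 100 splits drawn gives at least as many by construction (100 of 100, highest other 51), and the comparison says nothing about chance.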
